A study of Homo sapiens with 8 samples.

How the data were processed

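RNA levels were measured in 8 cultures of CEM, a human cell line derived from a T-cell acute lymphoblastic leukaemia (T-ALL). Per the labels, 4 cultures received a scrambled control shRNA and 4 received an shRNA against ZMIZ1. The design text calls the replicates biological and not paired, so the replicate numbers were not used to join a control with a knockdown culture. Total RNA was isolated on silica columns, 250 ng of it was amplified and biotin-labelled by in vitro transcription from the 3' end, and the product was hybridized to Affymetrix HG-U133 Plus 2.0 arrays.

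The authors deposited a log2 value for each of 54675 probe sets on each array, made with RMA (background correction, quantile normalization between arrays and summary per probe set). RMA is named in the submitters' processing notes; its version is not given in the sources used here. A deposited workbook holds the same log2 values, with a largest difference of 5.0e-09, beside the authors' group means as log2 values, a p-value from the methods' t-test and a ratio of knockdown over control. The p-value that the authors deposited is unadjusted and comes from a 2-sample test of the log2 values; it was matched by an equal-variance 2-sample test of the same values to within 1.75e-07. The deposited ratio is the anti-log of the difference of the group means. The values were used as deposited, without a further filter. Arrays give no counts, so the number of arrays, 4 per group, limits the precision.

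Differences were computed as knockdown minus control on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 6 residual degrees of freedom). The 62 control probe sets of the manufacturer were left out, which left 54613 probe sets. Benjamini-Hochberg adjustment was made over all of them, and adjusted p under 0.05 was the threshold. For counts of genes, each gene with 1 symbol was represented by its probe set with the highest mean over all 8 arrays, a choice that does not use the groups. The files pair 41479 probe sets with a single symbol, 961 with several and 12225 with none; 40270 of the single-symbol probe sets were matched to a current symbol by gene ID. This gave 20282 genes, of which 10740 had more than 1 probe set, and adjusted p values of genes were taken over these 20282. Errors of group means are SD over the 4 arrays, errors of differences are the standard errors of limma, and confidence intervals are at 95%.

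A total of 23 gene lists with 456 entries was fixed before the data were examined, as were the tests, the named genes and all alternatives not described below as added; 5 list entries were not measured. Each list was tested with camera of limma, which compares its members with all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 23 lists. The correlation was also estimated from the data, and fry of limma, which tests the members against no change and not against other genes, was run with statmod 1.5.0. Members that rose or fell are those past the threshold over all genes; the count adjusted over the list alone is given beside it. The mean of a list's members on each array was compared between groups with an exact two-sided permutation test over the 70 assignments of 8 arrays to groups of 4, in which the smallest possible p is 0.0286. The same test was used for ZMIZ1 and for the quality measures.

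The named genes were ZMIZ1, ZMIZ2, MYC, NOTCH1, HES1, DTX1, NRARP, IL7R and PTCRA; the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean was at least 6; and up to 4 members of each list past the threshold with the largest differences, or the member with the smallest p where none passed. This rule took 98 genes. Where a list had few changed members, those outside the rule were named as well, after their values were seen, and these were not run under the alternatives. Among the named members of a list, those whose call held with each array left out are given first.

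The fit was checked on simulated arrays of the same size and design with 54613 probe sets. It recovered 6% of 50 probe sets simulated at a 1.25-fold change, 76% of 50 at 1.5-fold, 98% of 50 at 2-fold and 100% of 50 at 4-fold, with 7 calls among 54413 unchanged probe sets. A simulated shift of -0.30 in the MYC target list was called, and 0 of the 22 other lists were called with it by camera. Probe sets and genes were simulated independently of each other, so these checks do not give the rate of false calls among correlated genes. Far fewer probe sets were changed in the simulation than the 7592 called in the real arrays. The Benjamini-Hochberg limit was thus stricter there, so the recovered shares do not carry over to the real fit. In the real arrays the estimated correlation was 0.42 for the MYC targets and 0.72 for the unfolded protein and amino acid stress response list.

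The alternatives were the replicate number as a block, a further quantile normalization, centring of each array on its median, removal of dim probe sets, the values of the workbook, a mean-variance trend with robust estimation, array weights, an equal-variance test without moderation, each array left out in turn, an adjusted p under 0.01, the mean of all probe sets of a gene, removal of probe sets with the suffix _s_at or _x_at, the estimated correlation, fry, and removal of dim list members. A further pair was chosen after seeing the data, when the control probe sets for 18S ribosomal RNA differed between groups: the 18S signal of each array as a covariate, which left 5 residual degrees of freedom, and the knockdown arrays 1 and 2 only. Another 3 gene lists were also chosen after seeing the data. Raw array images were not analysed here.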

Results

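RNA from 4 control cultures and 4 ZMIZ1 knockdown cultures of the T-ALL cell line CEM was profiled on 8 arrays. The median log2 value of an array lay between 5.15 and 5.20, and arrays of the same group correlated with each other with r from 0.992 to 0.997 across probe sets, which are not independent replicates. The control probe sets for 18S ribosomal RNA, a measure of residual ribosomal RNA in the labelled target, separated the groups. Their mean signal was 13.09 ± 0.29 in the control arrays and 10.96 ± 1.10 in the knockdown arrays (SD, n = 4; exact permutation p = 0.0286), a 4.38-fold difference. The values of each gene group were therefore also computed with the 18S signal as a covariate, an alternative chosen after seeing the data. All differences below are knockdown minus control on the log2 scale.

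ZMIZ1, a PIAS-like transcriptional coactivator and the target of the shRNA, was lower in every knockdown array than in every control array. The brightest of its 3 probe sets had a log2 value of 11.16 ± 0.06 in controls and 9.95 ± 0.14 in knockdown arrays (SD, n = 4; exact permutation p = 0.0286, the smallest that 70 assignments can give). ZMIZ1 thus fell by 1.21 ± 0.08 (SE; adjusted p = 0.000109 over all probe sets), to 43.2% of the control level. The other 2 ZMIZ1 probe sets were dim, with control means of 5.38 and 5.25 and differences of -0.10 and -0.07 that did not pass the test. Its paralog ZMIZ2 had a difference of -0.13 ± 0.11 and did not pass (adjusted p = 0.472).

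The comparison asks which transcripts of a T-ALL line differ when an shRNA lowers ZMIZ1. The labels name no second shRNA against ZMIZ1 and no rescue. An effect of the shRNA on other transcripts therefore cannot be told apart from the loss of ZMIZ1. Of 20282 genes, 4486 (22.1%) changed, of which 2990 rose and 1496 fell, with a median size of 1.34-fold. A change of at least 2-fold was reached by 100 genes, 44 higher and 56 lower; the balance turned with arrays centred on their median (53 higher and 51 lower) and with the equal-variance test (42 and 36). The groups did not overlap in 5102 genes (25.2%), against 2.86% by chance. Among 54613 probe sets, 7592 changed (4579 rose and 3013 fell); of the 420 changed at least 2-fold, 99 rose and 321 fell. In the authors' deposited table, 3980 probe sets had a p under 0.01 and over a 1.3-fold difference, 2611 higher and 1369 lower. At their stricter limit, a 2-sample p under 0.0005 and over 2-fold, 88 passed, 53 higher and 35 lower. The excess of falls among 2-fold changes was thus absent there. Of 3704 genes with several probe sets and a call on at least 1, 179 had calls in both directions.

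The number of changed probe sets was 4454 without control replicate 3, 4788 without knockdown replicate 3 and 4438 without knockdown replicate 4. In the fit with the 18S covariate 48 probe sets (30 rose and 18 fell) and 246 genes (115 rose and 131 fell) passed. Among those that passed, the excess of rises was thus kept for probe sets and not for genes. With knockdown arrays 1 and 2 only, 1943 probe sets and 1889 genes passed. The 18S covariate raised the median standard error of the changed probe sets from 0.0972 to 0.163 and lowered the median size of their changes, taken in the direction of the change, from 0.47 to 0.34. Of the 97 named genes besides ZMIZ1, 91 passed, and 66 of these also passed with each array left out in turn; with the 18S covariate 71 of the 91 lost their call. The 20 that kept it were 9 of the 12 largest rises (ID1 and H2AC6 among them), 5 of the 12 largest falls (VEGFA among them), and HK2, CD1A, CCR7, XBP1, BCL2L2 and DUSP6.

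The largest rises were in SVOPL, a transporter-like gene (1.82 ± 0.17, SE), SH3TC1 (1.79 ± 0.20), EDIL3, which encodes a secreted integrin ligand (1.72 ± 0.15), and ID1, an inhibitor of basic helix-loop-helix transcription factors (1.61 ± 0.17). ACYP2, an acylphosphatase, rose by 1.52 and TWF1, an actin-binding protein, by 1.35. The remaining 6 were TP53INP1, H2AC6, CREBRF, GTF2IRD2, DNAJB2 and EMP3, with rises from 1.22 to 1.27. The adjusted p of these 12 genes ranged from 1.44e-05 to 0.00631. Other probe sets of SH3TC1 (0.17), EDIL3 (-0.11 and -0.08), TWF1 (-0.01 to 0.55), TP53INP1 (0.19 and 0.11) and GTF2IRD2 (0.18) did not pass. Of the 4 others of CREBRF, 2 rose (0.76 and 0.96), and the rest (0.07 and -0.19) did not pass. In the 18S covariate fit 9 of the 12 passed; the calls of TP53INP1, CREBRF and EMP3 ended (adjusted p = 0.0732, 0.260 and 0.420), with differences of 1.23, 1.23 and 0.55. The equal-variance test ended the call of CREBRF (adjusted p = 0.0744).

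The largest falls were in DDIT4L, an inhibitor of mTOR signalling (-1.97 ± 0.25, SE), VEGFA, the vascular endothelial growth factor (-1.89 ± 0.25), and NFU1, an iron-sulfur cluster protein of mitochondria (-1.88 ± 0.09). ASS1, which makes argininosuccinate in arginine synthesis, changed by -1.60, ITGA6, a laminin receptor subunit, by -1.39, INHBE by -1.73 and LRRC18 by -1.36. ZNF800 (-1.78), ANKRD36 (-1.52), USP44 (-1.52), ZNF37BP (-1.42) and LRRFIP1 (-1.42) complete the 12, with adjusted p from 2.56e-06 to 0.0218 over the set. With the 18S covariate VEGFA, NFU1, ASS1, ITGA6 and LRRC18 still passed, while the differences of ZNF800 (0.02), ANKRD36 (-0.08), ZNF37BP (-0.49) and LRRFIP1 (-0.72) shrank and their calls ended; DDIT4L (-2.05), INHBE (-2.07) and USP44 (-0.92) also no longer passed (adjusted p from 0.0619 to 0.989 for these 7). The differences of VEGFA and ASS1 grew with the covariate, to -2.26 and -2.13. From control replicate 1 to 4 VEGFA (8.43 to 9.81), ASS1 (9.11 to 10.62), DDIT4L, INHBE, USP44 and ITGA6 climbed, against the 18S signal. ZNF800 and ANKRD36 declined over these arrays, and the others did neither throughout. Passing with the covariate thus does not exclude control cultures that differ among themselves. The call of USP44 ended without control replicate 3, knockdown replicate 3 or knockdown replicate 4 (adjusted p from 0.0586 to 0.0668). The equal-variance test ended the calls of ZNF800, INHBE, ANKRD36 and USP44 (adjusted p from 0.0597 to 0.138), and removal of _s_at and _x_at probe sets ended that of LRRFIP1 (0.123). The 3 other probe sets of VEGFA had smaller differences (-0.50 to -0.44), and 2 of them passed. Those of ZNF800 (-0.12) and ZNF37BP (-0.27) did not pass. The other probe set of ITGA6 fell by 2.42, and 5 of the 9 others of LRRFIP1 fell (differences of all 9 from -2.43 to 0.08).

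**Figure D1:**
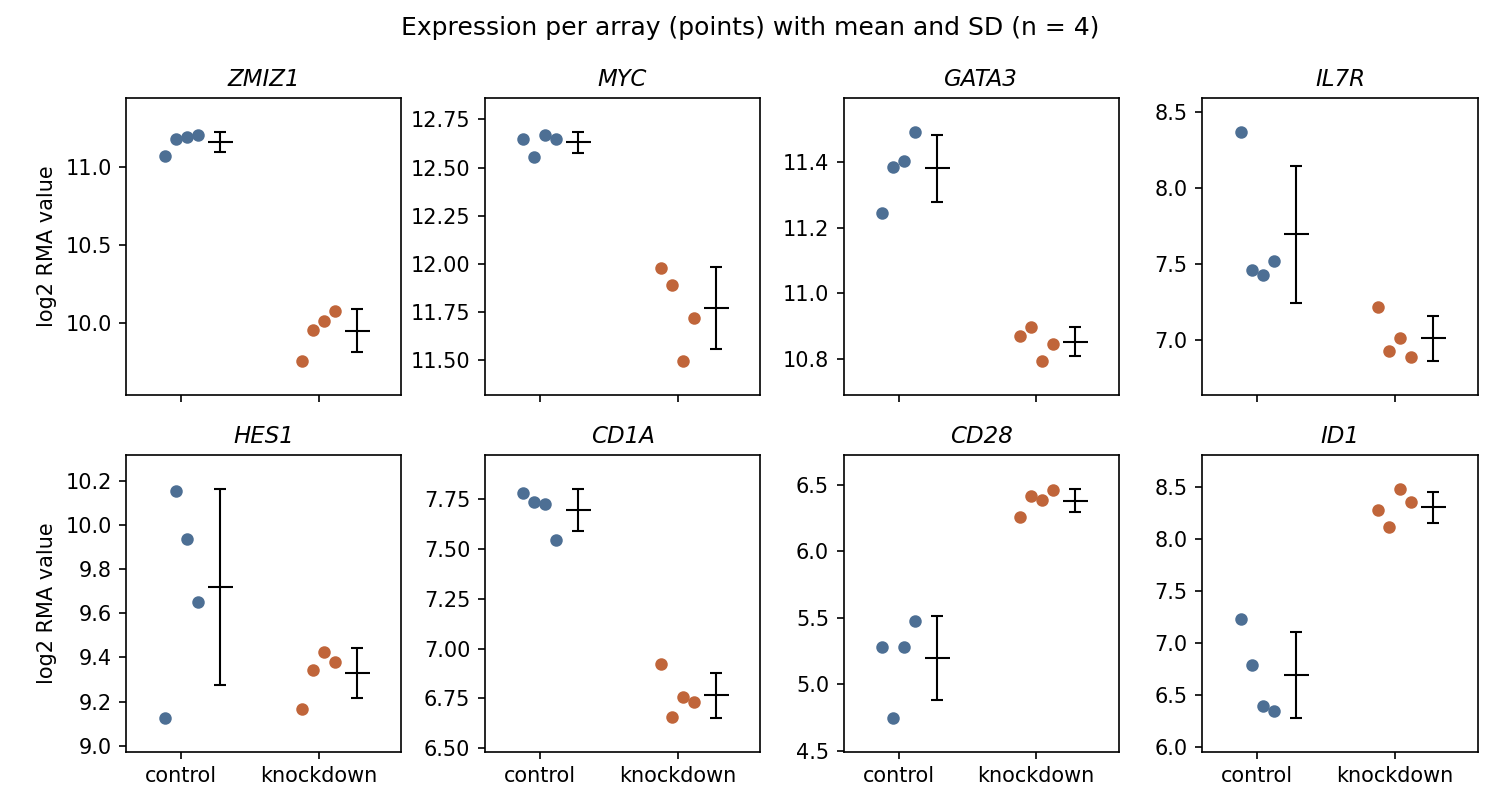
Log2 RMA values of 8 named genes on each array (points), with the mean and SD of the 4 arrays of each group beside them; each panel has its own vertical axis. ZMIZ1 lay at 11.16 ± 0.06 in controls and 9.95 ± 0.14 in knockdown arrays, and the groups overlap only in HES1.

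NOTCH1 is the oncogene that drives most T-ALL, and its target list was the first of the fixed lists. MYC, a NOTCH1 target in T-ALL, fell by 0.86 ± 0.10 (SE; adjusted p = 0.000233), from 12.63 ± 0.05 to 11.77 ± 0.21 (SD, n = 4). IL7R, the interleukin 7 receptor, fell by 0.68 ± 0.18 (adjusted p = 0.0177), and IGF1R fell by 0.47 ± 0.11 (adjusted p = 0.00960). HES4 (0.40), DTX1 (0.25) and HEY2 (0.23), which was named after its value was seen, rose. HES1, the NOTCH1 effector, had a difference of -0.39 ± 0.17 and did not pass (adjusted p = 0.138; confidence interval -0.77 to -0.01), although another of its probe sets fell by 0.73 (adjusted p = 0.000628 over all probe sets); its dim other probe set was higher by 0.18 and did not pass (adjusted p = 0.458). NOTCH1 itself (-0.08, confidence interval -0.26 to 0.10), NRARP (-0.18) and PTCRA (-0.07) did not pass, although a dimmer probe set of NOTCH1 (-0.28, adjusted p = 0.0453 over all probe sets) and another of PTCRA (-0.46, adjusted p = 0.0125) fell.

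Of the 18 NOTCH1 targets, 3 rose, 3 fell and 12 did not pass, over all genes and adjusted over the list alone; 14 were lower and 4 higher. The list mean was 7.46 ± 0.03 in controls and 7.31 ± 0.01 in knockdown arrays (SD, n = 4; exact permutation p = 0.0286), and the median of the members was -0.15, or -0.19 with the 18S covariate. Camera of limma called the list lower (adjusted p = 0.0462). That call was lost with an estimated correlation (adjusted p = 0.503), with the 18S covariate (adjusted p = 0.0740), after removal of _s_at and _x_at probe sets (adjusted p = 0.180), and without control replicate 2 (0.0606), control replicate 3 (0.0605), control replicate 4 (0.0542) or knockdown replicate 1 (0.0624). In fry, which tests the members against no change, the adjusted p was 0.000429. The calls of MYC, IL7R, IGF1R, HES4 and DTX1 ended with the 18S covariate, with differences of -0.42 for IL7R and -0.22 for IGF1R (adjusted p = 0.580 and 0.604). HES4 (0.48) and DTX1 (0.22) stayed near their size there, while their standard errors grew from 0.123 to 0.230 and from 0.0799 to 0.146. Among the members, the call of IL7R ended without knockdown replicate 4 (adjusted p = 0.0528). DTX1 no longer passed without any of the 4 control replicates or knockdown replicates 1, 3 and 4, each left out in turn (adjusted p from 0.0532 to 0.114). The same held for HES4 without control replicates 1, 3 and 4 and knockdown replicates 1, 2 and 4 (0.0578 to 0.0874). HES1 passed without control replicate 1 (adjusted p = 0.00589).

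MYC targets, mostly genes of ribosome assembly and nucleotide supply, were lower by less than MYC itself. HK2, a hexokinase, fell by 0.63 ± 0.07 (SE; adjusted p = 0.000186), NOLC1, a nucleolar protein, by 0.52 ± 0.08 and ODC1, the first enzyme of polyamine synthesis, by 0.44 ± 0.09. POLR1B, named after its value was seen (-0.38), and NIP7 (-0.47) also fell, so that of 40 members 0 rose, 5 fell and 35 did not pass; 4 fell adjusted over the list alone. Camera called the list lower (adjusted p = 0.00687), with a median of -0.10, or -0.05 with the 18S covariate; adjusted p = 0.518 with an estimated correlation, 0.230 with fry and 0.0636 with the 18S covariate. The list mean was 11.06 ± 0.17 in controls and 10.96 ± 0.04 in knockdown arrays (SD, n = 4; exact permutation p = 0.314), and without control replicate 1 the adjusted p of camera was 0.0852. MYC had a difference of -0.50 with the 18S covariate (adjusted p = 0.0952), and its dim second probe set one of 0.10 that did not pass. NOLC1 (-0.29) and ODC1 (-0.25) no longer passed with that covariate (adjusted p = 0.284 and 0.415). NIP7 no longer passed without control replicates 1, 2 or 3 or knockdown replicates 2, 3 or 4 (adjusted p from 0.0533 to 0.123), and its difference was 0.11 with the 18S covariate.

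Genes of T cell identity moved in both directions. CD28, a costimulatory receptor, rose by 1.18 ± 0.13 (SE; adjusted p = 0.000186) and CD3E, a chain of the T cell receptor complex, by 1.06 ± 0.12 (adjusted p = 0.000212). CD1A, a marker of cortical thymocytes, fell by 0.93 ± 0.08 (adjusted p = 6.39e-05), the homing receptor CCR7 by 0.67 ± 0.07 and the transcription factor GATA3 by 0.53 ± 0.07. Of 34 members of the T cell development and receptor list, 2 rose, 3 fell and 29 did not pass, adjusted over the list alone as well. The list was not called (camera adjusted p = 0.191, but 0.0250 and lower without dim members; median -0.06, or -0.11 with the 18S covariate). With the 18S covariate CD1A (-0.81) and CCR7 (-0.70) passed, while CD28, CD3E (0.66) and GATA3 (-0.51) did not (adjusted p from 0.0718 to 0.0965); GATA3 had an adjusted p of 0.0508 without _s_at and _x_at probe sets.

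Among 19 T-ALL oncogenes, 5 fell (MYC, IL7R, NKX2-1, TLX1 and HOXA10) and 2 rose (TAL1 and NKX2-5), adjusted over the list alone as well. TAL1, TLX1 and HOXA10 lie outside the rule and were named after their values were seen (0.40, -0.40 and -0.30). NKX2-1 fell by 0.50 ± 0.08 (SE; adjusted p = 0.00169), on an _x_at probe set; without _s_at and _x_at probe sets its difference was 0.06. NKX2-5 rose by 0.41, a call that ended without control replicates 1, 3 or 4 or knockdown replicates 3 or 4 (adjusted p from 0.0843 to 0.116), and its difference was 0.049 with the 18S covariate. The mean of the list was 8.53 ± 0.01 in controls and 8.42 ± 0.02 in knockdown arrays (SD, n = 4; exact permutation p = 0.0286), with a camera adjusted p of 0.0647. It was called lower with array weights (adjusted p = 0.0447) and fry (0.00386), and without dim probe sets (0.0479), control replicate 1 (0.0419) or knockdown replicate 2 (0.0455). Of 12 targets of the TAL1 complex, PCDH10 rose (0.80 ± 0.19), GATA3 fell and 10 did not pass (camera adjusted p = 0.0901), the same counts as adjusted over the list alone; this list was called lower without dim members (0.00883) or knockdown replicate 2 (0.0455). The medians of both lists were -0.10 and -0.09, or -0.06 and -0.04 with the 18S covariate.

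Genes of G2 and mitosis leaned higher. CDC25C, the phosphatase that activates CDK1, rose by 0.61 ± 0.11 (SE; adjusted p = 0.00219) and BUB1B, a spindle checkpoint kinase, by 0.35 ± 0.08 (adjusted p = 0.00689). Of 26 members 8 rose, 0 fell and 18 did not pass (9 rose and 1 fell adjusted over the list alone), with a median of 0.14 and the same 0.14 with the 18S covariate, but the list was not called (camera adjusted p = 0.0647). It was called higher with the mean-variance trend (adjusted p = 0.0392), array weights (0.0447), fry (0.0456) and knockdown arrays 1 and 2 only (0.0220), and without dim members (0.0469), control replicate 4 (0.0210) or knockdown replicate 3 (0.0256). The calls of CDC25C (0.47) and BUB1B (0.19) ended with that covariate (adjusted p = 0.266 and 0.491). Of 27 genes of S phase and DNA replication, CCND3 (0.40), CCNE2 (0.36) and MCM5 (0.34) rose, CDT1 (-0.26) fell and 23 did not pass; 0 passed adjusted over the list alone with limma, where 8 had an unadjusted p under 0.05, and the list was not called (adjusted p = 0.856; median 0.02, or 0.01 with the 18S covariate). The calls of these 4 genes were each lost without 1 array: CCND3 without control replicates 1, 2 or 3 or knockdown replicates 3 or 4, CCNE2 without control replicates 2, 3 or 4 or knockdown replicates 1, 2 or 4, MCM5 without control replicates 2, 3 or 4 or knockdown replicates 3 or 4, and CDT1 without control replicates 1, 3 or 4 or knockdown replicates 1, 3 or 4. Their adjusted p then ranged up to 0.125, 0.0888, 0.127 and 0.135. CCND3 had a difference of -0.12 with the 18S covariate, MCM5 one of 0.10 and CCNE2 one of 0.70, and CDT1 one of 0.02 with the mean of its probe sets.

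The unfolded protein and amino acid stress response list, made of genes induced by ATF4 and XBP1, held the most falls. XBP1 fell by 0.93 ± 0.11 (SE; adjusted p = 0.000322) and ASNS, asparagine synthetase, by 1.02 ± 0.20 (adjusted p = 0.00419). SESN2 (-1.03 ± 0.32) and CHAC1 (-1.01 ± 0.32) fell as well. Of 25 members 0 rose, 11 fell and 14 did not pass (12 fell adjusted over the list alone), with a median of -0.44, or -0.53 with the 18S covariate. Camera called the list lower (adjusted p = 4.51e-05), a call lost with an estimated correlation (adjusted p = 0.503). In fry the adjusted p was 0.157. The list mean ranged from 10.32 to 11.12 over the control arrays and from 10.30 to 10.43 over the knockdown arrays (n = 4; exact permutation p = 0.114). SESN2 lost its call without control replicates 3 or 4 or any 1 knockdown replicate (adjusted p from 0.0664 to 0.109), and CHAC1 without control replicates 2, 3 or 4 or any 1 knockdown replicate (0.0619 to 0.121). The calls of ASNS (-1.23), SESN2 (-1.73) and CHAC1 (-1.57) ended with the 18S covariate (adjusted p from 0.139 to 0.209). ASNS had a difference of -0.18 on its other probe set, which did not pass.

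The hypoxia and glycolysis list was lower in part. VEGFA fell by 1.89, PDK1, which limits entry of pyruvate into the citric acid cycle, by 0.73 ± 0.14 (SE; adjusted p = 0.00306) and HK2 by 0.63. Of 22 members 7 fell, 12 did not pass and 3 rose (ANKRD37, 0.45; PFKP, 0.39; SLC2A1, 0.28; each named after its value was seen); 9 fell and 3 rose adjusted over the list alone. Camera called the list lower (adjusted p = 0.00969; median -0.18, or -0.26 with the 18S covariate), with adjusted p = 0.503 with an estimated correlation, 0.150 with fry, 0.0917 without _s_at and _x_at probe sets and 0.0542 without control replicate 4. The list mean ranged from 9.10 to 9.68 in control arrays and from 9.02 to 9.21 in knockdown arrays (n = 4; exact permutation p = 0.114).

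Immediate early genes, which respond to growth factor and receptor signals, were lower on all 4 knockdown arrays than on any control array (list mean 6.78 ± 0.06 against 6.98 ± 0.09, SD, n = 4; exact permutation p = 0.0286). DUSP6, a phosphatase induced by and acting on ERK, fell and was 2.38-fold lower (adjusted p = 0.000394) and IER3 fell by 0.54 ± 0.08 (SE; adjusted p = 0.000855). With MYC, EGR1 (-0.49) and NR4A3 (-0.27, named after its value was seen), 5 of 22 members fell, 0 rose and 17 did not pass; 6 fell and 1 rose adjusted over the list alone. Camera called the list lower (adjusted p = 0.00969; median -0.10, or -0.21 with the 18S covariate), with adjusted p = 0.503 with an estimated correlation, 0.0422 with fry, 0.358 without _s_at and _x_at probe sets and 0.0528 without knockdown replicate 1. EGR1 lost its call without control replicates 2, 3 or 4 or knockdown replicates 1 or 4 (adjusted p from 0.0543 to 0.0769).

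Histone genes were higher, and 7 of them rose. H2AC6 rose by 1.26 ± 0.09 (SE; adjusted p = 1.44e-05), H2BC12 by 0.58 ± 0.11 (adjusted p = 0.00273), and the dim H2BC4 and H2BC21, with control means of 4.02 and 4.01, by 1.04 and 0.58. Of 14 members 7 rose, 0 fell and 7 did not pass, adjusted over the list alone as well. Camera called the list higher (adjusted p = 0.00829; median 0.29, or 0.16 with the 18S covariate), with adjusted p = 0.503 with an estimated correlation, 0.00386 with fry, 0.0636 with the 18S covariate, 0.0852 without dim probe sets (0.0165 without the dim members of the lists) and 0.267 without _s_at and _x_at probe sets. The list mean was 8.33 ± 0.11 in controls and 8.70 ± 0.11 in knockdown arrays (SD, n = 4; exact permutation p = 0.0286). The calls of H2BC12 (0.25), H2BC4 (0.65) and H2BC21 (-0.01) ended with the 18S covariate (adjusted p from 0.231 to 0.986).

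Cholesterol genes split: CYP51A1 (-0.47), HMGCS1 (-0.42) and FDPS (-0.39), all enzymes of sterol synthesis, fell, and SREBF2, the transcription factor that induces them, rose by 0.40. The other 20 of 24 did not pass, the same counts as adjusted over the list alone, and the list was not called (camera adjusted p = 0.0961; median -0.07, or -0.19 with the 18S covariate). It was called lower with the 18S covariate (adjusted p = 0.000409), with knockdown arrays 1 and 2 only (0.0140) and without knockdown replicate 4 (0.0453). SREBF2 lost its call without any 1 control replicate or knockdown replicates 3 or 4 (adjusted p from 0.0553 to 0.108), and its difference was -0.12 with the 18S covariate. In the glucocorticoid response list FKBP5 fell by 0.55 ± 0.08 (SE; adjusted p = 0.00103), SGK1 fell by 0.27, and 10 of 12 did not pass (3 fell adjusted over the list alone; camera adjusted p = 0.0827; median -0.16 with and without the 18S covariate). That list was called lower with array weights (adjusted p = 0.0447) and without dim members (0.0381), control replicate 1 (0.0136) or knockdown replicate 2 (0.0455). The difference of SGK1 was -0.052 with the 18S covariate (adjusted p = 0.909), and its call was lost without any 1 control replicate or knockdown replicates 1, 3 or 4 (adjusted p from 0.0604 to 0.143).

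In the BCL2 family, regulators of mitochondrial apoptosis, members of opposite function rose together. The proapoptotic BAD rose by 0.78 ± 0.12 (SE; adjusted p = 0.00130), the antiapoptotic BCL2L2 by 0.62 ± 0.10 and BCL2L1 by 0.51 ± 0.08, and PMAIP1, a proapoptotic gene, fell by 0.66 ± 0.11 (adjusted p = 0.00181). With BAK1 (0.50) and BAX (0.32), named after their values were seen, 5 of 15 rose, 1 fell and 9 did not pass (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.112, but 0.0408 and higher without _s_at and _x_at probe sets; median 0.20, or 0.13 with the 18S covariate). The calls of BAD (0.64), BCL2L1 (0.30) and PMAIP1 (-0.33) ended with that covariate (adjusted p from 0.195 to 0.377). The other probe set of BCL2L2 had a difference of -0.14 and did not pass. Over all alternatives the difference of BCL2L2 went down to 0.24 and its adjusted p up to 0.0728. Of 22 p53 targets, 5 rose (TP53INP1, TP53I3, SESN1, BAX and POLH, the last 2 named after their values were seen), PMAIP1 fell and 16 did not pass, with the same counts adjusted over the list alone. TP53INP1 rose by 1.27 and SESN1 by 0.40, and TP53I3 rose by 0.41, a call lost without knockdown replicate 3 (adjusted p = 0.0545). The p53 list was not called (camera adjusted p = 0.804), and its summaries differ in sign: the median was -0.03 (-0.02 with the 18S covariate), the mean 0.05, the direction of camera lower and that of fry higher.

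Interferon response genes, which shRNA can induce, did not move as a list (camera adjusted p = 0.400; median 0.08, or 0.05 with the 18S covariate). IRF9 rose by 1.01 ± 0.12 (SE; adjusted p = 0.000335), IFIT3 by 0.89 ± 0.16, OAS3 by 0.54 ± 0.14 and IRF7 by 0.45 ± 0.08. With RIGI (0.28) and IFITM1 (-0.27), named after their values were seen, 5 of 27 rose, 1 fell and 21 did not pass, adjusted over the list alone as well. With the 18S covariate the differences of IRF9, IFIT3, OAS3 and IRF7 were 0.51, 0.30, 0.02 and 0.31, and none passed (adjusted p from 0.124 to 0.981). OAS3 lost its call without knockdown replicate 4 (adjusted p = 0.0522).

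TGF-beta and SMAD targets were led by the ID genes: ID1 rose by 1.61, ID2 by 0.87 ± 0.12 (SE; adjusted p = 0.000571) and ID3 by 0.72 ± 0.14 (adjusted p = 0.00335). TGFB1 (0.62) and TGIF1 (0.36) rose and SMAD2 (-0.58) fell, the last 2 named after their values were seen, and 13 of 19 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.255; median 0.08, or 0.06 with the 18S covariate). The calls of ID2 (0.65), ID3 (0.49) and TGFB1 (0.39) ended with that covariate (adjusted p = 0.154, 0.355 and 0.435), and that of ID1 did not. TGFB1 had a difference of -0.16 without _s_at and _x_at probe sets. In the PIAS and SUMO pathway, to which ZMIZ1 is related by its zinc finger, PIAS3 rose by 0.54 ± 0.08 (SE; adjusted p = 0.00112) and PIAS4 by 0.43 ± 0.10, and SUMO2 fell by 0.42 ± 0.07 (adjusted p = 0.00182). Of 17 members 7 rose, 1 fell and 9 did not pass (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.195; median 0.18, or 0.15 with the 18S covariate). PIAS3 (0.28), PIAS4 (0.28) and SUMO2 (-0.30) no longer passed with it (adjusted p = 0.285, 0.486 and 0.259). Of 12 chromatin partners of ZMIZ1, SMARCB1 rose by 0.31, ETS1 (-0.37) and CREBBP (-0.27) fell and 9 did not pass (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.400; median -0.02, or -0.10 with the 18S covariate). ETS1 lost its call without control replicates 3 or 4 or knockdown replicates 3 or 4 (adjusted p from 0.0570 to 0.0781), and CREBBP without control replicates 2 or 3 or knockdown replicates 1 or 2 (0.0552 to 0.0717).

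**Figure D2:**
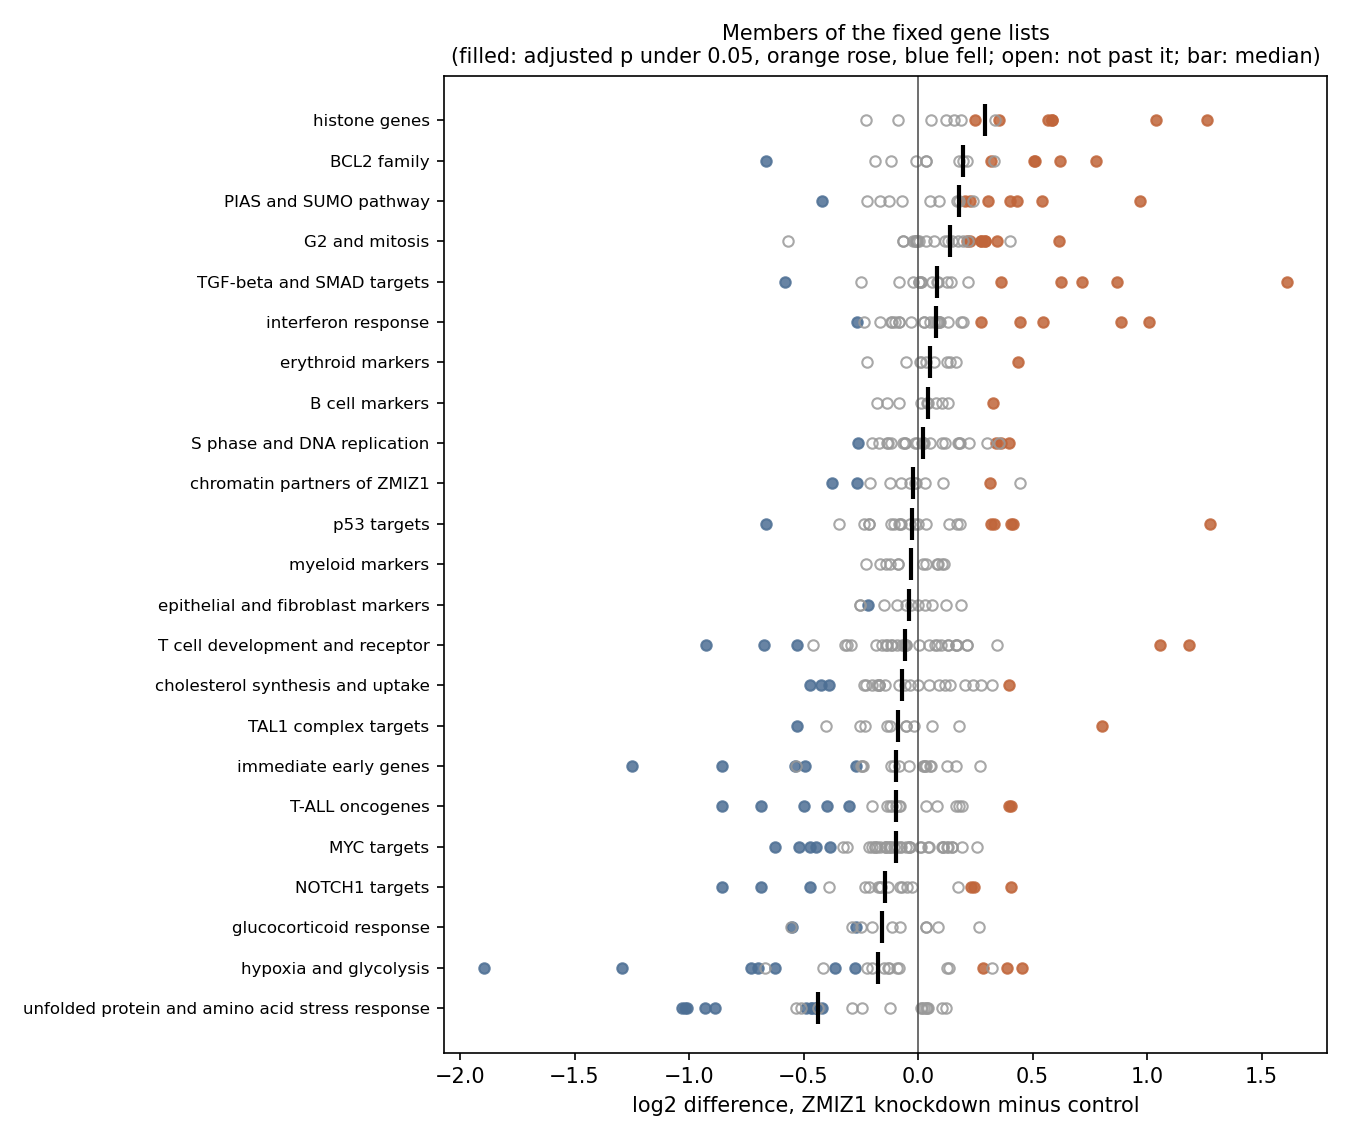
Log2 difference (knockdown minus control) of each measured member of the 23 fixed lists, sorted by the list median (bar); filled points passed the test over all genes, orange for rises and blue for falls, and open points did not. The stress response list has the lowest median (-0.44) and the histone list the highest (0.29).

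Markers of other cell types gave no list-level difference: camera adjusted p was 0.999 for B cell, 0.400 for myeloid, 0.672 for erythroid and 0.191 for epithelial and fibroblast markers. VPREB1 (0.33), HBB (0.44) and KRT8 (-0.22) were the only members of these lists that passed; of the 12 myeloid markers 0 passed with limma and 1 had an unadjusted p under 0.05, S100A8 (-0.23, adjusted p = 0.0947). Adjusted over the list alone, 1 B cell marker and 1 erythroid marker rose and 0 others passed. The medians were 0.04, -0.03, 0.05 and -0.04, or -0.04, -0.03, -0.09 and -0.17 with the 18S covariate. KRT8 lost its call without control replicates 2, 3 or 4 or any 1 knockdown replicate (adjusted p from 0.0598 to 0.109).

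With the preset correlation camera called 6 of the 23 lists, 5 lower and 1 higher. With an estimated correlation camera called 0 (lowest adjusted p = 0.503), and 2 had an unadjusted p under 0.05 (NOTCH1 targets and T-ALL oncogenes). The adjustment gave many lists this same 0.503. Their unadjusted camera p differed. It was 0.0349 for NOTCH1 targets, 0.0792 for histone genes and 0.0991 for immediate early genes. For hypoxia and glycolysis it was 0.195, and for the stress response 0.261. In fry 8 lists passed. NOTCH1 targets, T-ALL oncogenes and immediate early genes were lower in it. G2 and mitosis, the BCL2 family, TGF-beta and SMAD targets, PIAS and SUMO pathway and histone genes were higher. In the test of fry for change in either direction, 22 lists had a p under 0.05. On the level of list means, the groups did not overlap in 7 lists. NOTCH1 targets, T-ALL oncogenes and immediate early genes were lower, and the BCL2 family, TGF-beta and SMAD targets, PIAS and SUMO pathway and histone genes were higher. The lists that were lower share members, so their results are not independent. MYC (-0.86) belongs to each of them, and IL7R (-0.68) to the NOTCH1 targets and the T-ALL oncogenes. Their means without these genes were not tested.

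Besides 18S ribosomal RNA, the array median separated the groups, at 5.18 to 5.20 in controls and 5.15 to 5.18 in knockdown arrays without overlap (n = 4; exact permutation p = 0.0286). The other quality measures overlapped between the groups. The difference between 3' and 5' probe sets was 0.24 ± 0.08 in controls and 0.30 ± 0.01 in knockdown arrays for GAPDH (SD, n = 4; exact permutation p = 0.314) and 1.45 ± 0.71 and 1.95 ± 0.45 for ACTB (exact permutation p = 0.286). The 4 hybridization spikes gave exact permutation p values of 0.0857 or more. The 18S signal ranged from 12.70 to 13.37 over the control arrays, and was 12.12 and 11.67 in knockdown replicates 1 and 2 and 9.85 and 10.21 in knockdown replicates 3 and 4. The 321 probe sets that fell at least 2-fold lay at a median of -0.82, -0.96, -1.80 and -1.57 relative to the control mean in knockdown replicates 1 to 4, and the 99 that rose at 1.01, 1.09, 1.32 and 1.20.

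**Figure D3:**
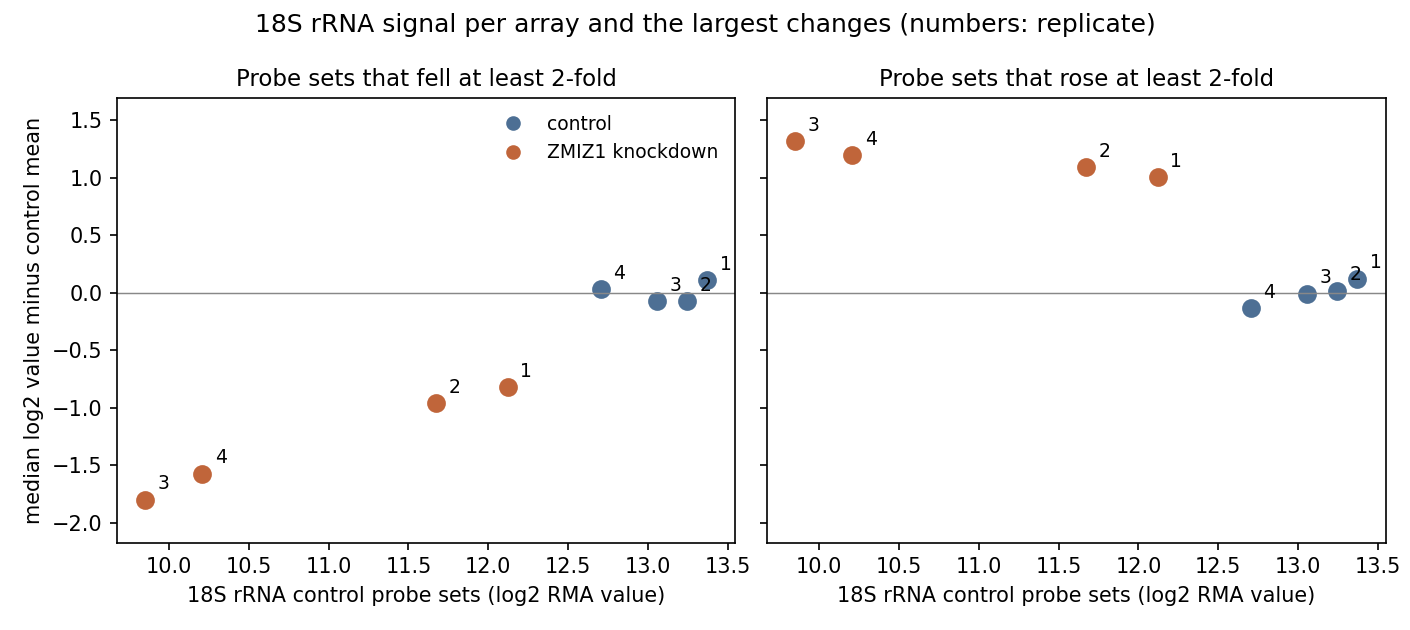
Median log2 value, relative to the control mean, of the 321 probe sets that fell (left) and the 99 that rose (right) at least 2-fold on each array, against the mean log2 signal of the 18S ribosomal RNA control probe sets; numbers are replicates. The fallen probe sets lie at -1.80 and -1.57 in the knockdown arrays with the lowest 18S signal and at -0.82 and -0.96 in the other two.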

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

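Counts over other splits of the 8 arrays were chosen before those counts were seen, except that for changed probe sets; the tests against the 18S signal, the ZMIZ1 level, the brightest probe set of a gene and the spread of the control arrays were chosen after the result was seen. The 8 arrays can be split 4 against 4 in 35 ways. For changed genes (4486), genes changed at least 2-fold (100) and changed probe sets (7592), only 1 split, the real one, gave a count as large. The highest count of any other split was 0 with limma (up to 2521 genes had an unadjusted p under 0.05 in another split, against 6918). Every other split mixes control and knockdown arrays, so a difference between the groups adds to its residual variance and favours a count of 0. The arrays thus separate by label, which a difference in 18S signal could give as well as the knockdown. For the NOTCH1 target list 1 split, the real one, gave a camera p as small as 0.0121, and the smallest of the other splits was 0.0159. The smallest share that this count can give is 1 of 35, and it was made for each list without adjustment. With so small a margin it does not exclude chance for this list. The call of that list was lost with an estimated correlation (adjusted p = 0.503) and without control replicates 2, 3 or 4 or knockdown replicate 1 (adjusted p from 0.0542 to 0.0624). For the number of lists called, 6 in the real split, 5 splits gave as many or more, and the highest count among the others was 8. The counts of splits given here include the real one. Chance is thus not excluded for this number. It is also not excluded for the MYC targets (15 splits, smallest other 7.79e-11 against 0.000597), the stress response (11 splits, 2.99e-16 against 1.96e-06), hypoxia and glycolysis (11 splits, 1.50e-07 against 0.00211), immediate early genes (5 splits, 0.000173 against 0.00210) and histone genes (4 splits, 0.000197 against 0.00108).

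Among probe sets more fell (321) than rose (99) by at least 2-fold. With arrays centred on their median 292 fell and 126 rose, and with the equal-variance test 100 fell and 89 rose. At the authors' limit, an unadjusted 2-sample p under 0.0005 and over 2-fold, 35 were lower and 53 higher. The excess of the 321 falls thus depends on the test and its threshold. Loss of the whole transcript as the cause of all these falls is argued against: in the 215 genes whose 2-fold fall was on a probe set other than the brightest, the brightest had a median difference of -0.20 (quartiles -0.43 and -0.01), while the fallen probe sets, which were selected for a large fall, had one of -1.28. A fall of the transcript stays open for part of them: 90 of these 215 brightest probe sets were called lower, 5 higher and 120 not, and 51 further falls were on the brightest probe set itself. The ZMIZ1 values did not point to a stronger knockdown in the arrays where these probe sets are lowest. Their median was -0.89 in the knockdown arrays with the lower ZMIZ1 values and -1.69 in those with the higher, a difference of 0.79. This comparison cannot decide the question, because the ZMIZ1 values of knockdown replicates 1 to 4 were close (9.76, 9.95, 10.01 and 10.07). The same arrays are also set apart by their 18S signal. A difference between arrays that follows the 18S rRNA signal, such as one in RNA preparation, may account for most of the pattern: with the 18S covariate the falls kept 30.2% of their median (-1.29 to -0.39) and the rises 1.01 of 1.13, with 13 and 15 probe sets still past the threshold. Among the falls the median difference shrank while the median standard error stayed near 0.27 (0.267 and 0.264). Still, 60 of the 321 kept a fall of at least 2-fold in size, more than the 13 that passed. Smaller differences thus do not account for every lost call. Among the rises the median standard error grew from 0.143 to 0.248, and 50 of the 99 kept that size. An effect of ZMIZ1 on the processing of transcripts or on 18S itself stays open and was not tested, because the 18S signal differs between the groups.

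The stress response list was lower in the knockdown arrays. The 18S signal did not account for this fall in the covariate fit, where the list kept 121% of its median (-0.44 to -0.53). Group and 18S signal correlated at -0.84 over the 8 arrays, so that fit separates them poorly. From control replicate 1 to 4 the list mean rose (10.32, 10.66, 10.91 and 11.12) while the 18S signal fell (13.37, 13.24, 13.06 and 12.70). Another gradient over the arrays was not tested. Control cultures that differ among themselves in this response are a candidate explanation: the SD of the list mean was 6.25 times as large over the control arrays as over the knockdown arrays, and 1 control array lay within the range of the knockdown arrays. A response to the loss of ZMIZ1 stays open as well (exact permutation p = 0.114 for the list mean).

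The MYC target list was lower in the knockdown arrays, and the same candidate explanation applies. Control cultures that differ among themselves in these genes are consistent with an SD of the list mean 4.33 times as large over the control arrays, with 2 control arrays at or under the highest knockdown array (exact permutation p = 0.314). With the 18S covariate the list kept 54.2% of its median (-0.10 to -0.05). A difference that follows the 18S signal and an effect of lower MYC cannot be told apart for this list, because both differ between the groups. The hypoxia and glycolysis list had an SD 3.12 times as large over the control arrays. In it 1 control array lay at or under the highest knockdown array. For the glucocorticoid response list, which was not called, the SD was 4.67 times as large, with 2 such arrays. Control cultures that differ among themselves thus stay a candidate explanation for these lists too.

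In 11 of 210 groups of 4 arrays checked for the named genes and measures, 1 array lay far from the other 3 for the spread of the group; chance gives 10.5. Of these, 10 were control groups, and the array was control replicate 1 in 7 of them. IL7R was at 8.37 in control replicate 1, with the other controls at 7.43 to 7.52. TWF1 was at 9.29 there, against 8.85 to 8.91. IGF1R was at 9.18 in control replicate 1, against 9.38 to 9.42. CCNE2 was at 10.59 in that array, against 10.35 to 10.39. CDC25C was at 7.95 in it, against 8.40 to 8.46. NKX2-1 was at 6.53 in it, against 6.27 to 6.30. CYP51A1 was at 10.84 in it, against 10.97 to 10.99. In control replicate 2, CDT1 was at 9.95, against 10.19 to 10.23, and NKX2-5 was at 11.05, against 10.60 to 10.66. TP53I3 was at 8.66 in control replicate 4, against 9.09 to 9.14. HK2 was at 9.67 in knockdown replicate 4, against 9.55 to 9.56 in the other knockdown arrays.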

How the results depend on the processing

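The 18S covariate and the use of knockdown arrays 1 and 2 only were chosen after seeing the data; the other alternatives were fixed earlier. ZMIZ1 remained lower and past the threshold under each alternative run for it. A further quantile normalization, centring on the median, the workbook values and the mean-variance trend left the counts of changed genes and probe sets within 1.5 times and kept the calls of the NOTCH1 and MYC target lists; centring moved the median difference of all probe sets to 0.04. With the replicate number as a block, a check only, since the replicates are not paired, 6698 probe sets and 3958 genes passed; deviations of control and knockdown arrays of equal number correlated at 0.06, -0.09, 0.05 and 0.05 across probe sets. Of the 4486 changed genes, 2658 also passed the equal-variance test and 229 the fit with the 18S covariate, in which 4303 kept their direction.

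Changed probe sets numbered 3910 with the equal-variance test, 2901 at adjusted p under 0.01, 48 with the 18S covariate and 1943 with knockdown arrays 1 and 2 only, against 7592; changed genes numbered 2860, 2281, 246 and 1889, against 4486. Among the 246 genes 115 rose and 131 fell, against 2990 and 1496, and among the 48 probe sets 30 rose and 18 fell, against 4579 and 3013. The stricter threshold and the fewer arrays lower such counts by construction. At least 2-fold changes were found in 66 genes with the mean of all probe sets and in 66 with knockdown arrays 1 and 2 only, against 100. Adjusted p of the NOTCH1 targets was 0.180 without _s_at and _x_at probe sets, 0.503 with an estimated correlation and 0.0740 with the 18S covariate; that of the MYC targets was 0.518 with an estimated correlation, 0.230 with fry and 0.0636 with the 18S covariate. Of the 21 other lists, 4 were called, against 7 with array weights, 7 with fry, 8 without dim members, 2 without _s_at and _x_at probe sets and 0 with an estimated correlation in camera, where 1 had an unadjusted p under 0.05. With the 18S covariate 4 were called as well, of which the cholesterol list gained its call (adjusted p = 0.000409) while the histone list lost it (0.0636). Among named genes past the threshold, directions turned for CDT1 (0.016) and NUSAP1 (-0.18) with the mean of all probe sets, for MYC (0.10), NKX2-1 (0.057) and TGFB1 (-0.16) without _s_at and _x_at probe sets, and for ZNF800 (0.017), NIP7 (0.11), CCND3 (-0.12), SREBF2 (-0.12) and H2BC21 (-0.013) with the 18S covariate; the probe sets of CDT1 and NUSAP1 are averaged there, and other probe sets stand for MYC, NKX2-1 and TGFB1. Among those not past it, HES1 (0.18) and S100A8 (0.094) were higher without _s_at and _x_at probe sets, and ZMIZ2 (0.074) with the mean. Beyond this the cause was not tested.

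With each array left out in turn, changed probe sets ranged from 4438 to 7430 (4454 without control replicate 3, 4788 without knockdown replicate 3, 4438 without knockdown replicate 4). The adjusted p of the NOTCH1 targets ranged from 0.0207 to 0.0624, past the threshold without control replicate 1 and knockdown replicates 2, 3 and 4, and lost without control replicates 2 (0.0606), 3 (0.0605) and 4 (0.0542) and knockdown replicate 1 (0.0624). That of the MYC targets ranged from 6.41e-05 to 0.0852, lost without control replicate 1, and 3 to 7 other lists were called, 7 without knockdown replicate 2. Of the 97 named genes besides ZMIZ1, 91 passed, and 66 of these passed with each array left out. In the fit with the 18S covariate 26 of the 97 kept their call or lack of one and 71 lost a call, 5 of them with a turned direction. With the mean of all probe sets 18 lost a call, and without _s_at and _x_at probe sets 12 did; the equal-variance test ended 33 calls. Dim probe sets limit what the arrays show: without them the histone list was no longer called (adjusted p = 0.0852), although it was without only the dim list members (0.0165), and the 2 dim ZMIZ1 probe sets changed by -0.10 and -0.07 where the bright one changed by -1.21.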

Other observations

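Autophagy genes were higher in the knockdown arrays, a group examined because TP53INP1 and CREBRF were among the largest rises. The 3 lists of this part and their tests were chosen after those results were seen; the counts over other splits of the arrays were fixed before they were made, except that without TP53INP1. Of 25 measured autophagy genes 17 rose, 0 fell and 8 did not pass, and the list mean was 8.45 to 8.50 on the control arrays and 8.81 to 8.96 on the knockdown arrays. ATG9A, a membrane protein of the early autophagosome, rose by 1.08 ± 0.11 (SE; adjusted p = 0.000138 with limma), ATG14, a subunit of the lipid kinase that starts autophagy, by 1.07 ± 0.08, the cargo receptor SQSTM1 by 0.71 ± 0.08 and GABARAP, which coats the membrane, by 0.65 ± 0.09. A wider rise of autophagy genes may accompany the loss of ZMIZ1: the camera p of the list was 1.63e-08. Of 35 splits 1, the real one, gave a p as small (smallest other 3.29e-06). This count cannot exclude chance, because the list was chosen from rises seen in that same split. The median difference was 0.40, or 0.19 with the 18S covariate, where the camera p was 5.41e-06. Part of the rise may thus follow the 18S signal. For that part, the 18S signal and the loss of ZMIZ1 cannot be told apart, because both differ between the groups. The adjusted p of camera over the 3 lists was 0.0747 with an estimated correlation. TP53INP1, whose rise led to the list, is 1 of the 25; without it the camera p was 7.37e-08, again the smallest of the 35 splits (smallest other 7.35e-06). The estimated correlation leaves the list short of the threshold, so the rise is a hypothesis from the same data, and RNA levels do not measure autophagy.

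Cytosolic aminoacyl-tRNA synthetases, which ATF4 induces together with ASNS, were mostly lower. Of 20 measured, 8 fell, 1 rose (HARS1, 0.40) and 11 did not pass; YARS1 fell by 0.69 ± 0.09 (SE; adjusted p = 0.000406 with limma) and GARS1 by 0.42 ± 0.10. A lower amino acid response in the knockdown arrays could also lower these genes, in line with a camera p of 1.00e-05 and a median of -0.23, or -0.26 with the 18S covariate. With an estimated correlation the adjusted p over the 3 lists was 0.118, and 2 of the 35 splits gave a p as small (smallest other 1.98e-06), so chance is not excluded. The list mean was 11.48 to 11.69 on the control arrays and 11.36 to 11.39 on the knockdown arrays.

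A shift of D cyclins, CDK inhibitors and MYC antagonists with lower MYC was tested as a further list of 24 genes. E2F7, a repressor of E2F targets, rose by 1.21 ± 0.08 (SE; adjusted p = 1.44e-05 with limma), the MYC antagonist MXD4 by 0.81 ± 0.10 and the CDK inhibitors CDKN2D and CDKN2C by 0.73 and 0.56, while RBL2, a relative of RB1, fell by 0.80 ± 0.11 and CCND2 by 0.71 ± 0.12. In all 7 rose, 4 fell and 13 did not pass. The list has members that should move in opposite directions, so its camera p of 0.702 and its median of 0.06 (0.05 with the 18S covariate) do not decide whether they respond together; 27 of the 35 splits gave a p as small (smallest other 0.0453). None of the 3 lists was run under the other alternatives.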
